A study of Mus musculus with 4 samples.

How the data were processed

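Gene expression was measured in BCR-ABL1-transformed mouse fetal liver lines on 4 two-colour Agilent arrays on 1 slide. Lines were wild type (WT) or carried Cdk4 R24C and Cdk6 R31C on both alleles (R/R), on a mixed C57BL/6J and CD-1 background. Per the labels, cells grew asynchronously, RNA integrity numbers were 9.8 to 10.0 and 100 ng of RNA was labelled. Clones 1, 2 and 3 (Cy5) were each hybridised with a WT pool (Cy3), and the R/R pool (Cy3) with the WT pool (Cy5). The labels speak of 3 control and 3 R/R replicates and do not say what the pools held.

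Per the file headers, the intensity values are median pixel brightnesses of spot and local background from Feature Extraction 11.5.1.1, uncorrected, with processed intensities that are background-subtracted and dye-normalised within the array. The log10 values are, per the file headers, log10 ratios of processed Cy5 over Cy3; they were exactly 0 for 19.3% to 27.6% of spots, none of them well above background. The log2 values deposited by the authors are R/R over WT ratios with the dye-swapped sign turned, whose making is not stated. By position they correlated with the ratios computed here at an absolute r of 0.986 to 0.997 across spots; their row numbers match no probe name, so they gave counts alone.

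Median spot and background intensities were used in place of the mean spot intensities that had been planned, a change made on seeing which columns the files held. With limma 3.58.1 in R 4.3.3, signals were normexp-corrected (offset 50) and loess-normalised within each array, with control spots given no weight. Between 210 and 265 spots per array marked non-uniform or as outliers were left out, and spots of a probe were averaged. Of 55681 probes 27656 had 1 gene symbol and 28025 had none here, and the latter were kept under their accession. Probes well above background in the R/R or the WT channel on at least 3 of 4 arrays were kept (26439), and the brightest probe per gene gave 20045 genes, 12296 of them with a symbol. Where a group or channel was not well above background, a fold given as at least a value is a bound. It was taken against the lowest signal called well above background in that channel or the measured signal, whichever was higher. Where the measured signal was higher, the bound equals the measured ratio and makes no allowance for error. For partly dim genes of that kind the fitted value with its SE is given. The bounds for single arrays and for partly dim genes were added after the data were seen.

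Each gene was fitted with limma with a genotype term and a dye term. The genotype value weighs the mean of the clones and the pool equally. The 2 residual degrees of freedom come from the clones, and the single WT pool adds no spread of its own. Tests were two-sided with Benjamini-Hochberg adjustment. Gene lists were tested with limma camera (correlation 0.01), with an estimated correlation and fry as alternatives. Adjusted p of lists are over 24 lists. With an estimated correlation, camera uses the 2 residual degrees of freedom, so it could hardly pass any list. Clone differences had no test. All arrays were on 1 slide, so there was no batch to test.

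The lists, tests, alternatives and rule for named genes were set before the data were examined. The rule took Cdk4, Cdk6 and the 4 INK4 genes; the 10 highest and 10 lowest called genes with a proper symbol and the same sign on 4 arrays; the 4 members with the smallest p of each primary list and each called secondary list; the 10 genes with the widest range over the clones; and sex-linked genes. Some genes that the rule took are not reported here. Alternatives were the scanner software's log ratios, offset 16, median centring, scaling between arrays, the deposited log2 table, no filter or a stricter one, the mean of probes or all probes, the clones alone, no dye term, each clone left out, clones 1 and 2 averaged, an intensity trend, and thresholds of 0.10 or 1.5-fold.

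The fit was tested on simulated data with 200 of 20045 genes changed. With an independent pool it recovered 2.99%, 53.7% and 97.0% of genes at 1.5-, 2- and 4-fold, with 4 false among 106 calls. With a pool mixing the 3 clones it recovered 10.4%, 70.1% and 98.5%, with 10 false among 129 calls. The simulations of the WT pool and of the shared reference were chosen after the data were seen.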

Results

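Gene expression was measured on 4 two-colour mouse arrays in cell lines grown out from fetal liver after transduction with p185 BCR-ABL1, the shorter fusion tyrosine kinase found in acute lymphoblastic leukaemia. The R/R lines carry knock-in point mutations in both alleles of Cdk4 (R24C) and Cdk6 (R31C), the cyclin D-dependent kinases that phosphorylate RB at the start of the cell cycle. These substitutions are known to stop INK4 proteins from binding the kinases. The comparison asked how the expression profile of R/R lines differed from that of wild-type (WT) lines transformed in the same way. RNA of R/R clones 1, 2 and 3 was labelled with Cy5 and hybridised, 1 clone per array, against a WT pool in Cy3. The remaining array carried an R/R pool in Cy3 against the WT pool in Cy5. Every ratio below is R/R over WT, with the sign of the dye-swapped array turned. Between 42.8% and 53.4% of spots lay well above background per channel, and replicate spots of a probe within an array had a median SD of 0.076 to 0.091 on the log2 scale. Between clones, each on its own array, the median SD was 0.17 over the 20045 genes tested. The number of arrays limits the precision.

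The mutated kinases showed no called difference in transcript level. Cdk4 had a log2 ratio of 0.21 ± 0.09 (SE of the fit, 3 clones and 1 pool, limma adjusted p = 0.340), and Cdk6 had 0.06 ± 0.09 (adjusted p = 0.789). Both genes carry point mutations in their own loci, so their transcript level does not check the genotype labels. Among the INK4 inhibitors, Cdkn2a, which encodes p16INK4a and ARF, had the highest value, 1.39 ± 0.22. It was higher on all 4 arrays, from 0.54 in clone 3 to 1.69 in clone 1, but did not pass the threshold (adjusted p = 0.086). Without clone 3 it passed, at 1.54 (adjusted p = 0.018). A second Cdkn2a probe gave 1.16, and neither probe was assigned to p16INK4a or to ARF. Cdkn2b had -0.15 ± 0.18 (0.07 by a dimmer probe), Cdkn2c had 0.31 ± 0.28 and Cdkn2d had -0.06 ± 0.13, and each of these 3 genes took both signs among the arrays.

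In R/R cells 30 genes were higher and 75 lower than in the WT pool, each with the same sign on all 4 arrays (limma, Benjamini-Hochberg adjusted p under 0.05). Of all 20045 genes, 6176 (30.8%) had 1 sign on the 4 arrays, which share the WT pool. A call needs a large value with clones close together, and the smallest called absolute log2 ratio was 0.74. The shared sign of the called genes therefore nearly follows from the call and is no separate evidence. The highest named genes were Ly6f, which encodes a GPI-anchored Ly6 protein, at 2.21 ± 0.13 (adjusted p = 0.010), and the aldehyde dehydrogenase gene Aldh1a7 at 2.06 ± 0.23 (adjusted p = 0.045). The actin-bundling plastin gene Pls3 stood at 1.46 ± 0.09 (2.75-fold). Its WT channel was well above background on only 1 of 4 arrays, so its rise may be larger. The phosphatidylcholine transfer protein gene Pctp rose to 1.43 ± 0.13 and Tmem273 to 1.42 ± 0.15. Eaf2 followed at 1.38 ± 0.17, the G protein signalling regulator Rgs10 at 1.25 ± 0.12, the chaperone genes Clgn and Hspb8 at 1.23 ± 0.14 and 1.18 ± 0.11, and Inpp5a at 1.09 ± 0.12. The second Eaf2 probe, a dim one, gave 0.37.

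Among the lowest named genes, the beta-defensin gene Defb45 stood at -2.59 ± 0.11 (6.04-fold higher in WT). The immediate early transcription factor gene Egr1 stood at -2.51 ± 0.11, and both had a limma adjusted p of 0.0068. Chac1, which encodes a glutathione-degrading enzyme, stood at -2.47 ± 0.12 (adjusted p = 0.0077), and the pseudokinase gene Trib3 at -2.27 ± 0.12 (adjusted p = 0.0093). The ubiquitin ligase genes Rnf130 and Mib2 were at -2.26 ± 0.26 and -1.73 ± 0.12, the histone demethylase gene Kdm5b at -2.11 ± 0.11 and Mgarp at -1.77 ± 0.15. Adult beta-globin Hbb-bt was at -1.84 ± 0.20 and embryonic Hbb-bh1 at -1.81 ± 0.11. The adult beta-globin genes are near-identical copies, so which of them the Hbb-bt probe measured is uncertain. Defb45 was well above background in the R/R channel on 3 of 4 arrays, so its fall may be larger. A second Defb45 probe, dim in every R/R channel, gave -2.29, and a second, dim Kdm5b probe gave -0.48.

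**Figure D1:**
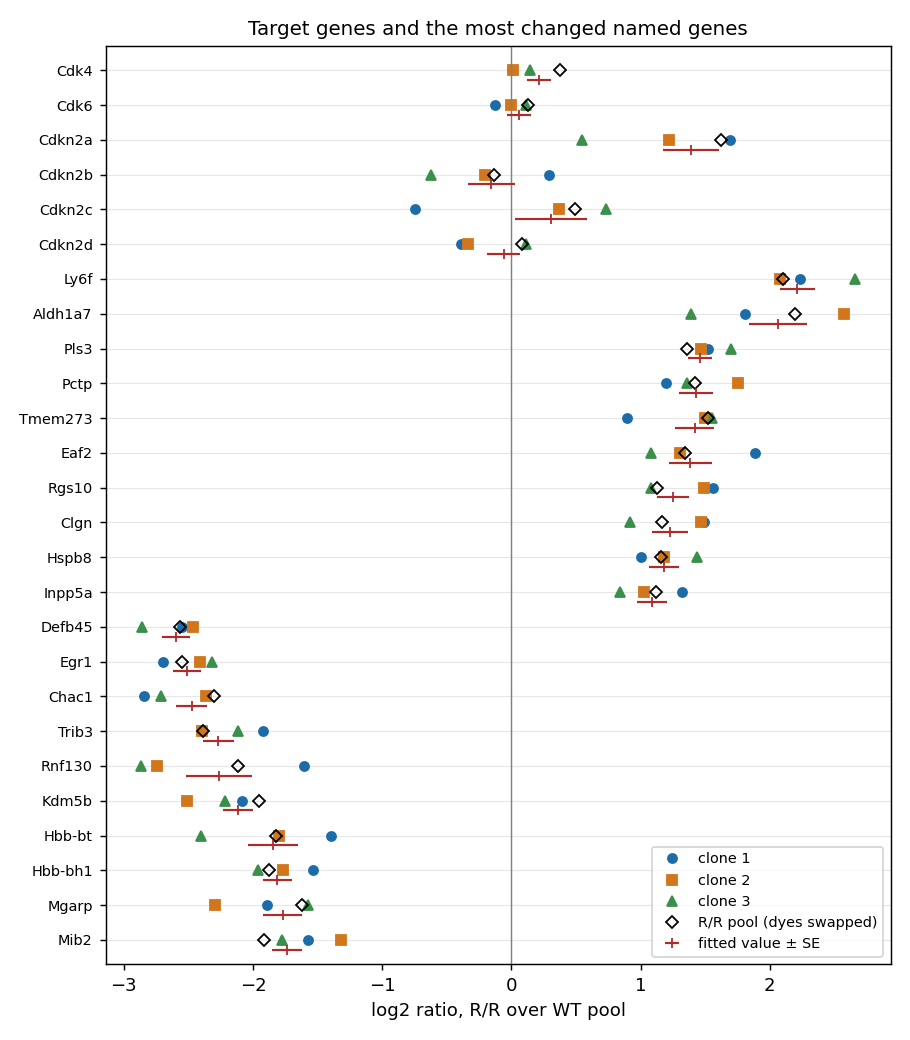
Log2 ratio of R/R over the WT pool on each array for Cdk4, Cdk6, the 4 INK4 genes and the 10 highest and 10 lowest named genes past the threshold. Filled symbols are clones, open diamonds the R/R pool, and the bar under each row is the fitted value with its SE; the called genes, taken among those with 1 sign on all 4 arrays, include Egr1 at -2.51 and Ly6f at 2.21, and Defb45 and Pls3, each with a dim channel on some arrays, are drawn as measured.

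The test used the spread among the 3 clones and left out the spread of the control, since 1 WT pool stood on every array. In 20 simulations with no genotype effect, a WT pool that deviated as much as 1 clone gave a median of 578 called genes (132 to 842). One that deviated as the mean of 3 clones gave a median of 0 (0 to 7). The 105 calls lay below the first range and above the second. What the WT pool held is not stated, and the simulated R/R pool was drawn independently of the clones. The simulations therefore leave open whether a deviating WT pool gave the calls. Without clone 1 the counts were 11 higher and 47 lower, and without clone 3 they were 88 and 176. With median centring in place of loess 2 genes were higher and 28 lower, and with the scanner software's log ratios 4 were higher and 42 lower. Counting the pool as another replicate, with no dye term, gave 490 and 650. Of the 29 called genes that the rule for named genes took, 11 lost their call without clone 1, 10 without clone 2 and none without clone 3. With the scanner software's log ratios 19 lost it, and with median centring 18. Of the highest and lowest genes, Clgn (limma adjusted p of 0.084 and 0.075), Inpp5a (0.074 and 0.075) and Rgs10 (0.060 and 0.063) lost it without clone 1 and without clone 2. Aldh1a7 lost it without clone 1 (adjusted p = 0.055), and Tmem273, Eaf2, Hspb8, Rnf130 and Hbb-bt without clone 2 (adjusted p of 0.062 to 0.079). All of these also lost it with the scanner ratios and with median centring. Pctp (adjusted p of 0.096 and 0.123) and Mib2 (0.052 and 0.069) lost it with these same settings, and Defb45 (0.054) and Mgarp (0.158) with the scanner ratios. The size of the ratios also moved with the processing, which the SE does not cover. With the scanner ratios the dimmer genes Defb45 (-4.24), Mgarp (-3.03) and Tmem273 (2.44) lay further from 0 than given above. The brighter genes Aldh1a7 (2.05), Eaf2 (1.35) and Hbb-bt (-1.91) stayed near the values given above.

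Among the lists fixed in advance that bear on CDK4/6, 3 of 6 shifted by camera with its preset correlation. None of these shifts passed with a correlation estimated per list. That version of camera rests on 2 residual degrees of freedom, and only 1 of 24 lists had an unadjusted p under 0.05 with it. The glycolysis list, with an estimated correlation of -0.03, below the preset 0.01, went from a camera p of 1.2e-09 to 0.021. For a list estimated below the preset, failing this version therefore decides little. Estimates were above the preset for cholesterol synthesis (0.42), NF-kB (0.20), ATF4 (0.12), G2/M (0.08), E2F (0.05) and ERK genes (0.05). They were below it for the other called lists. Where the estimate was higher, the preset may make p too small. All the list shifts stay uncertain. The list of E2F and DNA replication genes was higher (adjusted p = 0.024; adjusted p = 0.557 with an estimated correlation), although none of its 42 measured members passed alone, over all genes or adjusted over the list alone. Its median log2 ratio was 0.07, and 30 members were above 0. Among the members with the smallest p were the flap endonuclease gene Fen1 at 0.41 ± 0.11 (0.73 on the pool array, -0.14 to 0.26 in the clones), Slbp at 0.29 ± 0.10 and Chaf1b at 0.35 ± 0.12. The list of G2/M and mitosis genes was also higher (adjusted p = 0.019; adjusted p = 0.557 with an estimated correlation), with 24 of 37 members above 0 and none called over all genes. Adjusted over the list alone, 2 of its genes rose and 1 fell. Cyclin B1 (Ccnb1) stood at 0.76 ± 0.13 and Cdk1 at 0.49 ± 0.09, with 2 dimmer Cdk1 probes at 0.14 and 0.19, whereas the kinetochore gene Ndc80 stood at -0.55 ± 0.10 and Anln at -0.39 ± 0.09. In clone 3 the median of the replication list was -0.05 and that of the mitosis list -0.02, opposite to the other 3 arrays. Neither list passed without clone 2 (adjusted p = 0.057 for each), and the replication list did not pass on the clones alone (adjusted p = 0.303).

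The p53 target list was lower (adjusted p = 0.024; adjusted p = 0.468 with an estimated correlation). Of its 22 measured genes 2 fell, none rose and 20 did not pass. Adjusted over the list alone, 5 fell. Fitted values were below 0 in 14 members and above 0 in 8, among them Cdkn1a. Cdkn1a stood at 0.55 ± 0.37, from -0.72 in clone 3 to 1.14 in clone 1, and was named after its values were seen. The BH3-only gene Bbc3, which encodes PUMA, fell by 1.41 on the log2 scale (SE 0.12), a call lost with the scanner ratios (adjusted p = 0.096) and with median centring (adjusted p = 0.091). Sesn2, a stress-induced inhibitor of mTORC1 signalling, fell by 1.12 (SE 0.10), a call lost without clone 1 (adjusted p = 0.055), with the scanner ratios (adjusted p = 0.104) and with median centring (adjusted p = 0.135). Zmat3, with 3 of 4 R/R channels well above background, stood at -0.86 ± 0.11 (1.82-fold higher in WT), a difference that did not pass. Trp53inp1 stood at -0.67 ± 0.13, with a second, dimmer probe at -0.03. The list's median was 0.03 in clone 2 and between -0.22 and -0.10 on the other 3 arrays, and the call was lost without clone 3 (adjusted p = 0.099). The CDK4/6-INK4-RB axis did not shift as a list (camera adjusted p = 0.207, adjusted p = 0.557 with an estimated correlation). At probe level, where several probes of a gene count as separate members and p can be too small, it was higher (adjusted p = 0.028). Of its 25 genes 1 rose, E2f6, a repressive E2F family member, at 1.01 ± 0.12 (adjusted p = 0.049). E2f6 lost its call without clone 1 (adjusted p = 0.113), with the scanner software's log ratios (adjusted p = 0.156), with median centring (adjusted p = 0.102), and narrowly with offset 16, no filter or the mean of probes (adjusted p of 0.052 to 0.061). Adjusted over the list alone 2 rose. The CDK inhibitor gene Cdkn1b stood at -0.54 ± 0.13 and cyclin D3 (Ccnd3) at 0.54 ± 0.15. The 13 STAT5 target genes did not shift (adjusted p = 0.273) and none was called, over all genes or adjusted over the list alone; Pim2 stood at -0.35 ± 0.10, Socs2 at -0.31 ± 0.09, Bcl2l1 at -0.26 ± 0.09 (-0.49 on the pool array, -0.13 to 0.05 in the clones; -0.07 by a dimmer probe) and Mcl1 at -0.23 ± 0.09. This list was lower without clone 1 (adjusted p = 0.049) and, on all 4 arrays, at probe level (adjusted p = 0.026), with the limit given above for probe level. On all 4 arrays it had an adjusted p = 0.835 with an estimated correlation. The 29 early B-lineage genes did not shift (adjusted p = 0.847) and none was called; adjusted over the list alone, 1 rose. Cd24a stood at 0.67 ± 0.11, Cd22 at -0.55 ± 0.12, Spib at -0.79 ± 0.19 and Pou2af1 at 0.34 ± 0.10.

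The strongest list shift was in ATF4 target and unfolded protein response genes, lower in R/R cells with a median log2 ratio of -0.74 (camera adjusted p = 1.2e-10; adjusted p = 0.468 with an estimated correlation). Of 22 measured genes 5 fell over all genes, and 15 fell and 2 rose adjusted over the list alone. Besides Chac1 and Trib3, the transcription factor genes Ddit3, which encodes CHOP, and Atf3 fell, to -1.55 ± 0.10 and -1.18 ± 0.10; the Atf3 call was lost without clone 1 (adjusted p = 0.056) and with the scanner ratios (adjusted p = 0.103). The other called member was the lipoprotein receptor gene Vldlr at -1.08 ± 0.13, and the members that rose adjusted over the list alone were the endoplasmic reticulum chaperone genes Hspa5 (0.65 ± 0.09) and Sdf2l1 (0.41 ± 0.09); these 3 genes were named after their values were seen. Glycolysis and hypoxia genes were lower as a list (median -0.36, adjusted p = 1.4e-08; adjusted p = 0.468 with an estimated correlation), with 22 of 24 members below 0. None was called over all genes, and 17 fell adjusted over the list alone. The glucose transporter gene Slc2a3 stood at -1.23 ± 0.20, Aldoa at -0.77 ± 0.14, Vegfa at -0.83 ± 0.16 and Pkm at -0.47 ± 0.09. By fry, the glycolysis list alone passed (adjusted p = 0.037), and the ATF4 list had an adjusted p of 0.074.

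**Figure D2:**
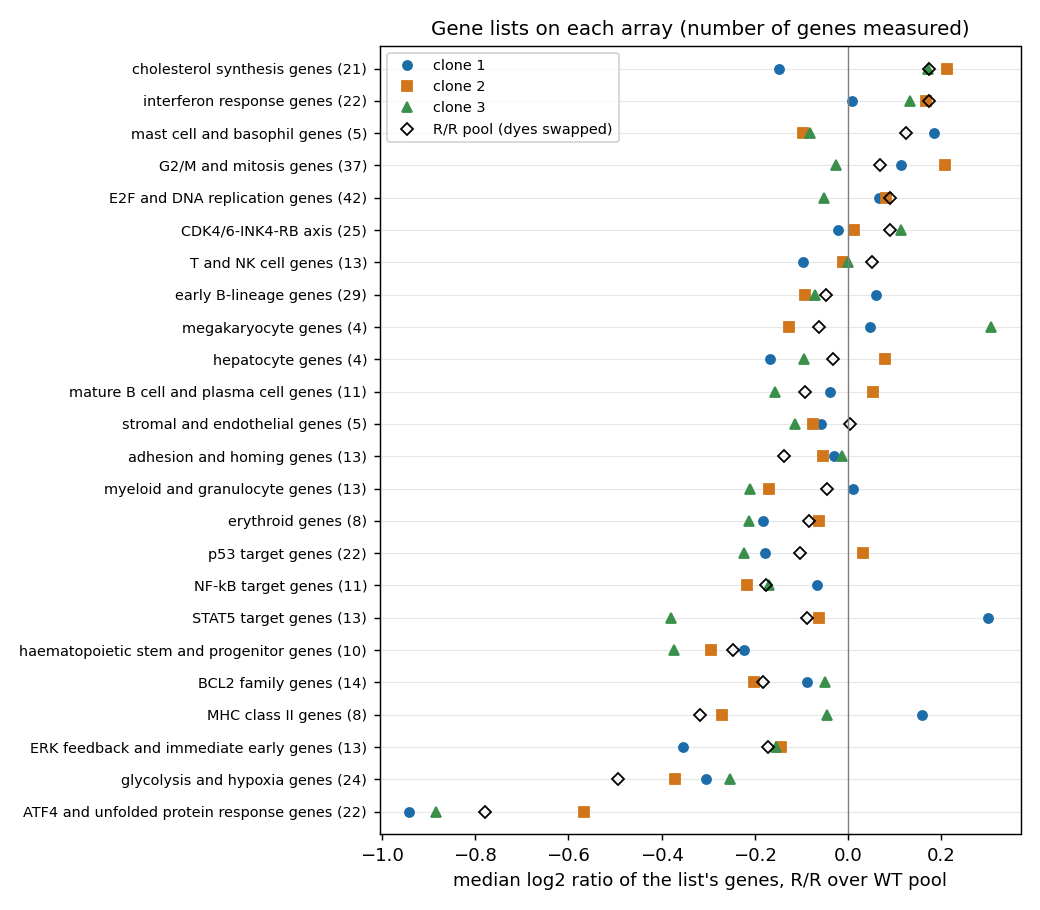
Median log2 ratio of R/R over the WT pool for each gene list on each array, with the number of genes measured in brackets; filled symbols are clones and open diamonds the R/R pool. The ATF4 list lies between -0.94 and -0.57 and the glycolysis list between -0.49 and -0.25 on the 4 arrays, and most other medians lie near 0.

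Of the other lists, 4 were lower and 2 higher with the preset correlation, and none passed with an estimated one. ERK feedback and immediate early genes were lower (adjusted p = 0.019; adjusted p = 0.468 with an estimated correlation), with Egr1 as the 1 called gene of 13; Ier2 stood at -0.52 ± 0.10, Dusp6 at -0.57 ± 0.14 and Spred1 at -0.43 ± 0.16, with its other probes at -0.42 and, a dim one, 0.02. Adjusted over the list alone, 3 fell. NF-kB targets were lower (adjusted p = 0.029; adjusted p = 0.59 with an estimated correlation), with 1 of 11 called, the activation marker Cd69 at -1.08 ± 0.09, and 2 adjusted over the list alone. Cd69 lost its call without clone 1 (adjusted p = 0.056), with the scanner ratios (adjusted p = 0.097) and with median centring (adjusted p = 0.123). Bcl3, with 2 of 4 R/R channels well above background, stood at -0.79 ± 0.13 (1.72-fold higher in WT) without passing. Tnf stood at -0.25 ± 0.09 and Nfkbie at -0.18 ± 0.10. Stem and progenitor genes were lower (adjusted p = 0.025; adjusted p = 0.468 with an estimated correlation); 1 of 10 was called and 4 fell adjusted over the list alone. The called gene, Hoxb4, was not well above background in any R/R channel and was at least 1.62-fold higher in WT (adjusted p = 0.048). It lost its call without clone 1 (adjusted p = 0.136), without clone 2 (adjusted p = 0.077), with median centring (adjusted p = 0.149), with scaling (adjusted p = 0.058) and with clones 1 and 2 averaged (adjusted p = 0.064). Mycn stood at -0.51 ± 0.13 and Lmo2 at -0.88 ± 0.23, and Slamf1, with 2 of 4 R/R channels well above background, was at least 1.25-fold higher in WT without passing. BCL2 family genes were lower (adjusted p = 0.044; adjusted p = 0.468 with an estimated correlation), with 2 of 14 called, Bbc3 and Bcl2a1d, and 3 adjusted over the list alone. This list lost its call in 10 of 17 alternatives, among them the strict filter (adjusted p = 0.156), the clones alone (adjusted p = 0.109), median centring and no dye term (adjusted p = 0.066 for each) and, narrowly, the scanner ratios and scaling (adjusted p = 0.051 for each). Bcl2a1d, well above background in 1 of 4 R/R channels, was at least 1.92-fold higher in WT and lost its call without clone 1 (adjusted p = 0.111) and without clone 2 (adjusted p = 0.062), as well as with the scanner ratios, median centring, scaling, no filter and the mean of probes. Bmf stood at -0.56 ± 0.09. Interferon response genes were higher (adjusted p = 0.011; adjusted p = 0.468 with an estimated correlation) with 18 of 22 members above 0, none called over all genes and 1 adjusted over the list alone. Xaf1 stood at 0.65 ± 0.12, Ifih1 at 0.39 ± 0.10 and Oas1a at 0.67 ± 0.25. Cmpk2, with 3 of 4 WT channels well above background, stood at 0.38 ± 0.11 (1.30-fold higher in R/R) without passing, and a second, dimmer probe gave 0.29. Cholesterol synthesis genes were higher (adjusted p = 0.0075; adjusted p = 0.611 with an estimated correlation), with 16 of 21 above 0, none called over all genes or adjusted over the list alone, and a median of -0.15 in clone 1 against 0.17 to 0.21 on the other arrays. On the clones alone the interferon list (adjusted p = 0.054) and the cholesterol list (adjusted p = 0.050) did not pass. Idi1 stood at 0.51 ± 0.11 and Mvd at 0.35 ± 0.16.

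Without clone 2, the ERK and the stem and progenitor lists (adjusted p = 0.057 for each), the NF-kB list (adjusted p = 0.101) and the BCL2 list (adjusted p = 0.131) did not pass, and the NF-kB list did not pass without clone 3 either (adjusted p = 0.066). The NF-kB list also lost its call with the scanner ratios (adjusted p = 0.103) and the strict filter (adjusted p = 0.118), and the stem and progenitor list with the strict filter (adjusted p = 0.171).

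Apart from the stem and progenitor list, no list of markers of another cell type was called. Of 8 measured erythroid genes 2 fell, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.077), although it did without clone 1 (adjusted p = 0.039, lower) and with the scanner ratios (adjusted p = 0.034, lower). On all 4 arrays it had an adjusted p = 0.611 with an estimated correlation. The genes that fell were Hbb-bh1 and Hbb-b2 (-1.32 ± 0.16), both beta-globins, while the alpha-globin gene Hba-a2, a dim one, stood at 0.02 ± 0.09; Hbb-b2 and Hba-a2 were named after their values were seen. MHC class II genes did not shift (adjusted p = 0.28), with none of 8 called over all genes or adjusted over the list alone, but were lower without clone 1 (adjusted p = 0.043). On all 4 arrays they had an adjusted p = 0.751 with an estimated correlation. Mature B and plasma cell genes did not shift (adjusted p = 0.534); 1 of 11 fell, and 1 rose and 2 fell adjusted over the list alone. None of the 13 myeloid genes was called over all genes, and 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.511 for the list). The same counts held among the 13 T and NK cell genes (adjusted p = 0.975). Of 4 megakaryocyte genes 1 rose adjusted over the list alone (adjusted p = 0.742), and none was called among 5 mast cell genes (adjusted p = 0.689), 4 hepatocyte genes (adjusted p = 0.975), 5 stromal and endothelial genes (adjusted p = 0.888) and 13 adhesion genes (adjusted p = 0.353). The signs of mean, median and test differed in the T and NK cell list (mean -0.05, median 0.01, test up), the hepatocyte list (mean 0.07, median -0.03, test down) and the megakaryocyte list (mean 0.05, median -0.02, test up).

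No gene was called for a difference between dyes (limma, adjusted p under 0.05), with 537 genes (2.7%) at an unadjusted p under 0.05 among 20045. Only the R/R pool array had swapped dyes, so the dye term cannot be told apart from a difference between clones and pool. If the pool mixes these clones, that difference varies less than the clones do, and the test could hardly call a gene. The median absolute dye term was 0.07 on the log2 scale. With median centring in place of loess, 6330 genes were called for dye.

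The R/R clones differed from each other in sets of single genes. The purine nucleoside phosphorylase gene Pnp2 stood at -5.24 in clone 2 against -0.09 and 0.50 in clones 1 and 3. Plscr1 and Txndc15 were not well above background in clone 1, and were there at least 6.82-fold and 13.0-fold higher in the WT pool, while the other clones lay between 0.16 and 1.66. Clone 3 was lowest in Klhl22 (-4.28, against -0.97 and -0.51 in clones 1 and 2) and Ifitm1 (-2.77, against 1.23 and -0.02). Clone 2 was lowest in Marcks (-2.21, against 1.70 and 1.93 in clones 1 and 3). Other genes with wide ranges were Akr1c13, from -3.48 to 0.75, and Nbdy, at 1.54 in clone 3 and at least 6.92-fold higher in the WT pool than in clone 1, where it was not well above background. The leukotriene receptor gene Cysltr1 stood at 3.83 in clone 3 and, as measured, was 5.65-fold higher than a dim WT channel in clone 1. In clone 2 Cysltr1 was not well above background. In all, 152 of 20045 genes spanned at least 4-fold over the 3 clones, and none of them was among the 105 called. There were 888 such genes with the scanner software's log ratios, 278 with offset 16 and 101 with the strict filter. With 1 array per clone these differences have no test. Each ratio already pairs an R/R sample with the WT pool on its array, and no further pairing was used.

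Clones 1 and 2, which share the first part of their clone number, differed by an SD of 0.36 across genes (log2), clones 1 and 3 by 0.38, and clones 2 and 3 by 0.46. Across genes, which are not independent replicates, the log2 ratios of the clones correlated at r = 0.45 (clones 1 and 2), 0.48 (1 and 3) and 0.23 (2 and 3). These ratios share the WT pool. Unchanged clones against a shared WT sample gave a simulated r of 0.51 where that sample varied like 1 clone and 0.24 where it varied like the mean of 3. The mean covariance observed, 0.050, lay between the simulated 0.083 and 0.026. The mean of the clones and the R/R pool correlated at r = 0.66, with the same limit.

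Sex-linked transcripts also set the clones apart. Xist, the RNA of the inactive X chromosome, stood at -0.14 in clone 3 and -1.32 in the pool. It was not well above background in clones 1 and 2, and was at least 3.06-fold and 4.10-fold higher in the WT pool on these arrays. The Y-linked gene Ddx3y stood at 2.71 in clone 2 and 1.79 in the pool, and was not well above background in clones 1 and 3. Eif2s3y was not well above background in any R/R channel, and was at least 1.95-fold higher in WT (adjusted p = 0.047), a call lost without clone 1 (adjusted p = 0.062) and with median centring, scaling and no filter. Kdm5d and Uty did not pass the filter on dim probes; Uty was well above background in clone 2 alone.

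**Figure D3:**
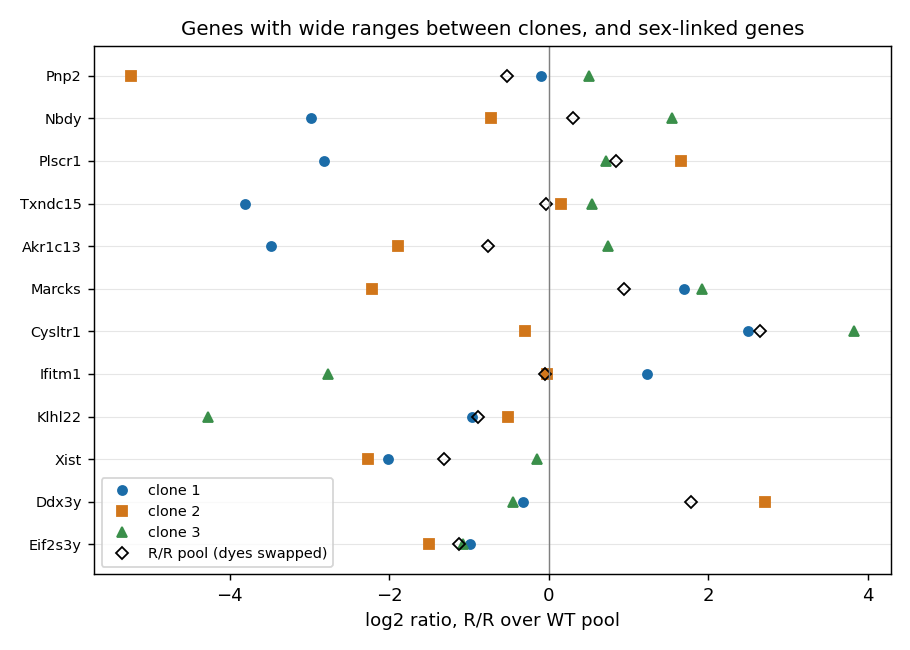
Log2 ratio of R/R over the WT pool on each array for named genes with wide ranges over the 3 clones and for the sex-linked genes tested; filled symbols are clones and open diamonds the R/R pool, 1 array each, and ratios with a channel not well above background are drawn as measured. Single clones stand far from the others, as in Pnp2 at -5.24 in clone 2 and Klhl22 at -4.28 in clone 3, while the pool lies within the range of the clones in each gene drawn.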

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

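None of these values was tested, and the criterion for dim probes was chosen after the data were seen. Probes left out of the test as dim gave signal in 1 clone alone, with no WT channel well above background and a measured ratio of at least 2-fold: 5 probes in clone 1, 16 in clone 2 and 13 in clone 3. Of the folds below, those of Mboat1 and Xlr4a are lower bounds, as the WT signal lay below the lowest signal called well above background. The other folds are measured ratios against a dim WT channel, with no allowance for error. In clone 1 Mboat1 was at least 4.20-fold higher than WT. In clone 2 there were 3 Y-linked genes, Gm20877 (3.22-fold higher), Sly (2.60-fold) and Ssty1 (2.45-fold). In clone 3 there were 3 X-linked genes of the Xlr family, Xlr4b (6.47-fold), Xlr4a (at least 5.06-fold) and Xlr3b (4.86-fold). These genes were named after their values were seen.

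The median of the 5 stromal and endothelial genes was 0.0048 on the R/R pool array and -0.06, -0.07 and -0.11 in clones 1, 2 and 3, opposite in sign. The difference was not tested.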

How the results depend on the processing

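All alternatives were set before the data were examined. Genes higher and lower in R/R numbered 4 and 42 with the scanner software's log ratios, 2 and 28 with median centring, 490 and 650 with no dye term, 107 and 203 at adjusted p under 0.10, and 61 and 139 of 59305 unnamed spots in the deposited table. At probe level 49 probes, not genes, were higher. Higher genes were 49 with scaling, and lower genes 48 with the strict filter. Leaving out 1 clone gave 11 to 88 higher and 47 to 176 lower genes, the lowest without clone 1 and the highest without clone 3. Of the 105 called genes, 28 were shared with the scanner ratios, 30 with median centring, and 43, 48 and 105 without clones 1, 2 and 3. Higher genes were 30 of 105, but 4 of 46 with the scanner ratios and 2 of 30 with median centring. The dye term called 6330 genes with median centring, which leaves intensity-dependent dye differences in, and 0 without clones 1, 2 or 3.

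With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 1. The test with an estimated correlation, on 2 residual degrees of freedom, could hardly call a list. On the clones alone 1 list was higher, and with the strict filter 3 were lower. Leaving out 1 clone gave 2 to 4 higher and 3 to 10 lower lists. The adjusted p of the E2F list was 0.125 with the scanner ratios, 0.557 with an estimated correlation, 0.303 on the clones alone, 0.204 with fry, 0.066 with no dye term, 0.053 with the strict filter and 0.014 to 0.057 leaving out 1 clone. That of the G2/M list was 0.557 with an estimated correlation, 0.335 with fry and 0.0063 to 0.057 leaving out 1 clone. That of the p53 list was 0.468 with an estimated correlation, 0.074 with fry, 0.135 at probe level, 0.118 with the strict filter and 0.017 to 0.099 leaving out 1 clone. The ATF4 list had 0.468 with an estimated correlation and 0.074 with fry, and the glycolysis list 0.468 with an estimated correlation. At probe level the RB axis (0.028) and STAT5 targets (0.026) passed, with 0.557 and 0.835 by an estimated correlation. Probe level counts several probes of a gene as separate members, which can make p too small. Leaving out 1 clone, STAT5 targets ranged from 0.049 to 0.976. Lists were not run under the intensity trend or on the deposited table.

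The SD between clones was 0.671, 0.690 and 0.819 (1 and 2, 1 and 3, 2 and 3) with the scanner ratios and 0.442, 0.461 and 0.555 with offset 16. Genes with a 4-fold range numbered 888, 278 and, with the strict filter, 101. No named gene or list that passed in either setting turned its sign. The cause of these differences was not tested. Between 42.8% and 53.4% of spots per channel were well above background, which limits what dim genes can show.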

Other observations

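All genes in this paragraph were named after their values were seen. Among B-lineage genes the complement receptor gene Cr2 fell, at -1.55 ± 0.09 (limma adjusted p = 0.010), on all 4 arrays. The BAFF receptor gene Tnfrsf13c stood at -0.79 ± 0.10 (adjusted p = 0.053) and Jchain, which encodes the immunoglobulin joining chain, at 1.21 ± 0.20 (adjusted p = 0.089). The MHC class II invariant chain gene Cd74 stood at -0.10 in clone 1 and at -1.37, -1.53 and -1.20 in clones 2 and 3 and the pool. Klrd1 stood at -1.20 ± 0.20 and Tcf7 at 0.65 ± 0.10, neither past the threshold over all genes.

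Of the tests below, the one on neighbours of the knock-in alleles was set before its result was seen (and limited to genes with a symbol after a first run, with the same outcome), and those on dye, on the WT pool and on the R/R pool were chosen after. ATF4 target and glycolysis genes were lower on all 4 arrays. Dye bias would turn the sign on the dye-swapped array, where the ATF4 median was -0.778 with 19 of 22 genes below 0, which argues against it. A state of the WT pool's own culture could give the same lower values, as 1 WT pool was on every array. The ATF4 medians of the R/R clones spanned 0.376 around a mean of -0.797, and no value from these arrays separates genotype from such a state. Both stay open.

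Genes linked to the knock-in alleles could carry variants of another strain and so differ whatever the mutation does. Among the 152 genes beside Cdk4 and Cdk6, 27 had an unadjusted limma p under 0.05 (17.8%). Of 10000 random window pairs, 53.45% had as high a share, so both sides together held no excess. The Cdk6 side alone had 14 of 52 (26.9%) and the Cdk4 side 13 of 100, against 18.5% of all placed genes. The windows held 1 called gene, Ddit3, which lies 10 tested genes from Cdk4. Neither a single side nor linkage of Ddit3 was tested. Genotype and the WT pool's state stay open for the called genes. Sex-linked transcripts also differed between the lines, and the Y-linked gene Eif2s3y was itself called. Eif2s3y was at least 2.24-fold higher in WT than in clone 2, although the Y-linked gene Ddx3y stood at 2.71 in that clone. Its call therefore did not follow the other Y-linked signal. Whether sex or the mixed background of the lines gave other calls was not tested.

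The R/R pool may hold RNA of these 3 clones. In 49 genes at least 4-fold higher in 1 clone than in both others, the pool lay above the mean of the others by a median of 1.54 (quartiles 1.15 to 2.08; 49 of 49 above), against 1.43 for an even mix. Best-matching shares were 24.2%, 52.5% and 23.3% for clones 1, 2 and 3. If so, the pool is no independent sample of R/R cells. No biological explanation was tested.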
